A study of Mus musculus with 6 samples.

How the data were processed

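The labels describe total RNA extracted with RNeasy kits, amplified and labelled with biotin by the TotalPrep-96 method, and hybridized to Illumina mouse bead arrays. The series covers 6 arrays, with 2 biological replicates per the design text of each of 3 lines: ES cells, the iPS line with the PB-Oct4.2A.cherry transgene (control iPS) and the clone of that kind marked low (Oct4-low iPS). The lines' sex, the passage, the chips on which the arrays lay and the dates of hybridization are not given in the sources used here.

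The deposited scanner table holds an intensity for each of 45281 probes on each array, the average bead signal per probe on a linear scale per the file headers, neither normalized nor log-transformed. Beside each signal the deposited table gives a detection p-value. It was taken to be the share of the array's negative controls with a signal at or above that of the probe. Its smallest nonzero value then implies 936 negative controls, a number that was inferred. The scanner software and its version are not given in the sources used here. The authors' own processed table holds log2 values for 16306 probes, between 6.95 and 15.1, with the same sorted values in every column to an SD of 0.000202, so it was quantile-normalized by the authors. Its transformation, software and filter are not given in the sources used here. As many probes, 16306, had a detection p under 0.01 on at least 1 array of the scanner table. The identifiers of the authors' table are of another kind than those of the scanner table and do not name genes there, so that table served only for counts of changed probes.

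Scanner signals were background-corrected with the nec function of limma 3.58.1 in R 4.3.3, which took the mean and spread of the negative controls from the detection p-values, with an offset of 16. They were then quantile-normalized over the 6 arrays and expressed as log2. Background correction spreads dim signals apart and quantile normalization forces the same distribution on every array, so a difference in total RNA per cell would be lost. Probes entered when their detection p was under 0.01 on both arrays of at least 1 group, which 14452 did. Probes were named by the current symbol of their gene (27760), by a synonym (7994) or by the definition (34), and 9493 kept the name in the file. For each gene the brightest probe over all 6 arrays was used, which left 10251 genes, of which 3062 had more than 1 detected probe. Chromosomes were taken from the gene reference and from the probe annotation for 9150 genes (89.3%), and where both named a chromosome they gave the same one for 99.9% of 7792 genes. Positions in the probe are not given in the sources used here, so no exon or untranslated region is stated for a probe.

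One group-means model was fitted to all 6 arrays with limma's lmFit and eBayes, and the 3 differences between groups were tested with it, two-sided. The spread is thus shared by the groups, with 3 residual degrees of freedom, or 6.87 with the prior. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 10251 genes were called, and "rose", "fell" and "changed" refer to such calls. The smallest absolute log2 difference called was 1.03 in control iPS over ES, 0.77 in Oct4-low iPS over ES and 0.83 in Oct4-low over control iPS, and the median standard error was 0.207. Simulated data of this size had 200 changed genes in each of 10 draws. The spread of a gene was the model's own estimate, shrunk by the prior and equal in all groups. Real replicate differences had an SD from 0.343 (Oct4-low iPS) to 0.461 (ES), so the shares called may be too high. The model called 46.9%, 43.0% and 48.8% of genes changed by 2-fold in the 3 comparisons. It called 98.8%, 98.3% and 98.3% of those changed by 4-fold, and 4.18%, 3.88% and 2.39% of those changed by 1.5-fold. It also called 9.8, 8.2 and 9 unchanged genes per draw on average. That is a larger share of the calls than the adjusted p threshold of 0.05 implies.

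Gene lists were fixed before the data were examined, as were the grouping, the tests, the thresholds, the rule for named genes and the alternative settings but one. The 29 lists were naive pluripotency factors, general pluripotency, Oct4-Sox2 target, primed epiblast, trophectoderm, primitive endoderm, neural, mesendoderm, two-cell-like, germline and imprinted genes, LIF-STAT3, Wnt, ERK, Nodal and BMP response or target genes, DNA methylation machinery, Polycomb, p53 target, ATF4 and amino acid stress, glycolysis, oxidative phosphorylation, cell cycle, cholesterol biosynthesis, fibroblast and feeder cell, epithelial and adhesion, sex-chromosome, interferon response and reference genes. Some genes stand in several lists; for example, 13 of 15 Oct4-Sox2 target genes and 10 of 16 naive factors are in another list as well. The 28 lists with at least 3 measured genes were tested with limma's camera, two-sided, with a preset correlation between genes of 0.01 and, beside it, with the correlation estimated for each list, and adjusted over the lists of a comparison. With an estimated correlation camera draws its p from the 3 residual degrees of freedom, so few lists can pass whatever their correlation.

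Genes were named by a rule. In each comparison these were the 10 largest rises and the 10 largest falls among called genes whose arrays of one group all lay above those of the other, leaving out predicted and clone-named genes; up to 4 members of each list with the smallest p. Always named were Pou5f1, Nanog, Sox2, Esrrb, Klf4, Zfp42, Cdx2 and Gata6 where measured. Across comparisons the rule named the 10 genes changed against ES cells in the same direction in both iPS lines with the largest smaller change, and up to 10 genes of opposite direction. A few of the genes so chosen are not named, although counts include them. Tubgcp4, Tmem87a and Clgn were named outside the rule, after their values were seen. Chromosomes were examined after the gene results had been seen, with camera over the 20 chromosomes, with 95% intervals of the median, and against 10000 random lists matched in expression. These intervals are over genes, taken as independent, and hold no spread between arrays.

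The alternatives tried were no background correction, median scaling in place of quantile normalization, no filter on dim probes, detection on all 6 arrays, every detected probe as its own feature, the mean of a gene's probes, each other probe of a named gene, only the 4 arrays of the groups compared, the replicate number as a block, an intensity trend with a robust prior, a minimum absolute log2 difference of 1, the authors' processed values, an estimated correlation for camera, and leaving out each of the 6 arrays in turn. One more, without the genes of chromosomes 6, 8 and X, was added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, from tables read with pandas 2.3.3. No array was left out of the values reported, and the number of arrays limits the precision of each.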

Results

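Gene expression was measured on Illumina mouse bead arrays in 3 kinds of pluripotent cell, with 2 biological replicates of each and 6 arrays in all. Embryonic stem (ES) cells were the reference. The other two groups were induced pluripotent stem (iPS) lines that are both marked -/- and named for a transgene joining Oct4, a 2A peptide and the red fluorescent protein cherry. Such a piggyBac (PB) transgene can supply Oct4 to cells that lack their own gene. The labels do not say what -/- refers to. The line without a further mark is called control iPS here, and the clone marked low is called Oct4-low iPS. All cells were labelled B6. They grew in knockout serum replacement medium with the cytokine LIF, 3 µM CHIR99021 (an inhibitor of GSK3) and 1 µM PD0325901 (an inhibitor of MEK). This combination is known to hold mouse cells in the naive state. Of 45281 probes, 13289 to 14295 were detected above background on each array (29.3% to 31.6%). The median signal per array lay between 87.3 and 96.0, and 10251 genes entered the tests. Across all probes, which are not independent replicates, the log2 signals of the 2 arrays of a group correlated with r = 0.990 in control iPS, 0.993 in Oct4-low iPS and 0.989 in ES cells. The number of arrays, 2 in each group, limits the precision of every value given here. Each group is a single line, so p-values and intervals measure the spread between replicates of a line, not between lines. Levels are mean log2 normalized intensity ± SD over the 2 arrays of a group, and folds carry the 95% confidence interval of the fit.

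Pou5f1, the gene on chromosome 17 that encodes Oct4, was brightest in ES cells and dimmest in Oct4-low iPS cells. Its brighter probe (address 7650296) read 12.18 and 12.21 on the ES arrays, 10.96 and 11.03 on the control iPS arrays, and 8.97 and 8.87 on the Oct4-low iPS arrays. Pou5f1 thus stood 9.68-fold lower in Oct4-low iPS than in ES cells (7.43 to 12.6, adjusted p = 0.000761, limma). It stood 4.21-fold lower than in control iPS cells (3.23 to 5.48, adjusted p = 0.00450). In control iPS cells it was 2.30-fold lower than in ES cells (1.77 to 2.99, adjusted p = 0.0269). The other Pou5f1 probe (address 3450519) gave log2 differences of -3.12, -1.70 and -1.42 for the same comparisons in the same order. No probe sequence is given, so it is unknown whether either probe sees the transcript of the transgene as well as that of the cells' own gene. Under 10 of 11 other settings of the processing the difference between control iPS and ES cells kept its call. On leaving out 1 array it did so only without ES replicate 1, with log2 differences between -1.24 and -1.16. Its adjusted p was 0.158 without control iPS replicate 1, 0.0824 without control iPS replicate 2, 0.128 without ES replicate 2, and 0.0868 without either Oct4-low iPS array or with only the 4 arrays compared.

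The other pluripotency regulators examined by rule in every comparison were not called in any of them. Nanog, a core factor of pluripotency, measured 12.41 ± 0.23 in ES, 12.42 ± 0.34 in control iPS and 12.78 ± 0.02 in Oct4-low iPS cells. Its fold between Oct4-low iPS and ES cells had an interval of 0.897 to 1.86. Esrrb, an orphan nuclear receptor of the naive network, measured 13.17 ± 0.08, 13.18 ± 0.03 and 12.75 ± 0.08 in the same order. Sox2, which binds DNA together with Oct4, differed by 0.42 on the log2 scale between Oct4-low iPS and ES cells (adjusted p = 0.225), Klf4 by -0.12 (adjusted p = 0.818) and Zfp42 by -0.57 (adjusted p = 0.343). In control iPS over ES cells the differences were 0.67, 0.41 and -0.55, and between the iPS lines -0.25, -0.53 and -0.02. Of the 14 measured naive pluripotency factors, limma called 0 in any of the 3 comparisons. At an unadjusted p under 0.05 there were 1, 5 and 5 in control iPS over ES, Oct4-low iPS over ES and Oct4-low over control iPS. Adjusted over the list alone, 0 passed in the first of these, 3 rose in the second, and 2 rose and 1 fell between the iPS lines. The list as a whole was not shifted in any comparison (camera adjusted p = 0.376, 0.812 and 0.673), though without ES replicate 1 it was higher in control iPS than in ES cells (median 0.41, adjusted p = 0.0266). In Oct4-low iPS over ES cells its median (-0.04) and mean (0.21) differed in sign. Cdx2, a trophectoderm factor that Oct4 is known to repress, was not detected on both arrays of any group and was not tested.

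**Figure D1:**
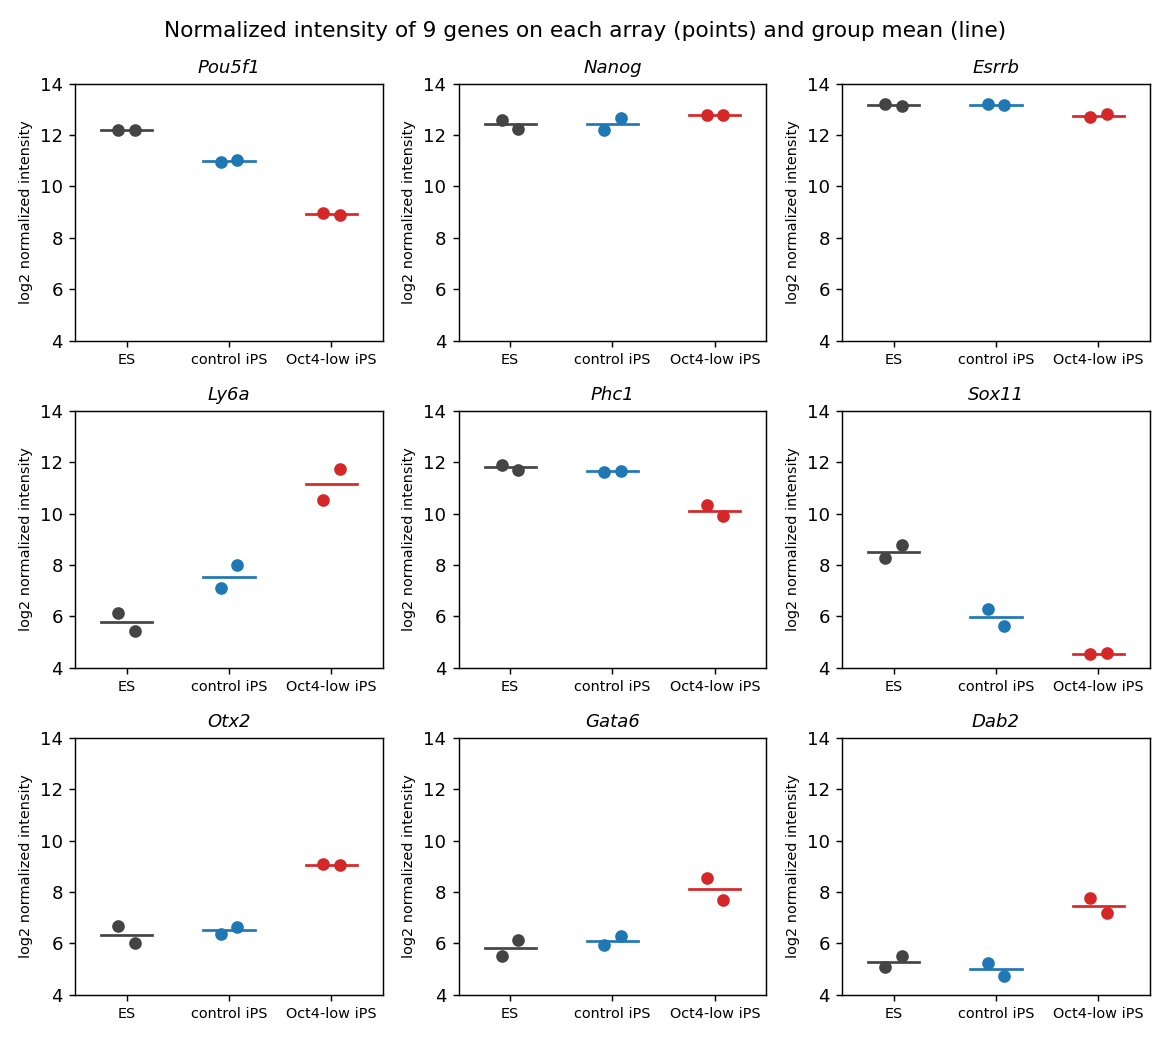
Normalized log2 intensity (vertical axis) of 9 genes on each array of ES, control iPS and Oct4-low iPS cells (horizontal axis); each point is 1 array and each line the mean of the 2 arrays of a group. Pou5f1 falls from 12.20 in ES to 8.92 in Oct4-low iPS cells, the Nanog means lie between 12.41 and 12.78, and Otx2, Gata6 and Dab2 are highest in Oct4-low iPS cells.

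Control iPS cells were compared with ES cells to ask how an iPS line that carries the Oct4 transgene differs from the reference. The gene with the greatest fall was Tomm22, an import receptor of the outer mitochondrial membrane, 33.6-fold lower in control iPS cells (24.0 to 47.1, adjusted p = 0.000446), although the other detected Tomm22 probe differed by 0.34 in the opposite direction. Thumpd1, an adaptor for tRNA acetylation, rose at least 12.8-fold (adjusted p = 0.000446). Baiap2l1, an actin-binding protein that bends membranes, rose 17.3-fold (11.9 to 25.0, adjusted p = 0.00114). Slc4a3, an anion exchanger, rose 13.0-fold (9.11 to 18.7, adjusted p = 0.00148). Folds written as at least are bounds for genes above background on no array of the dim group. For these the bright group's mean was divided by the dim group's mean of the higher of the probe's own signal and the lowest detected signal of the array. In all, 112 genes changed, 58 up and 54 down, and 41 had such a bound. At an unadjusted p under 0.05 there were 1635. The count of calls was 24 with no filter on dim probes, 22 with detection on all 6 arrays and 331 with the replicate number as a block.

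Other genes higher in control iPS than in ES cells were Cd3d (13.8-fold, 5.48 to 34.8) and Cd3g (11.1-fold, 6.25 to 19.7), both subunits of the T cell receptor complex. So were Akr1c18, a progesterone-converting steroid dehydrogenase (9.79-fold, adjusted p = 0.0263), Pnpla3, a lipid droplet lipase (7.66-fold, 5.24 to 11.2), Cited4 (at least 5.12-fold) and Olfml1 (5.40-fold, 3.26 to 8.95). Aqr, a helicase of the spliceosome, was 7.22-fold higher (5.25 to 9.93, adjusted p = 0.00241) by the probe used, while its other probe differed by -0.29. The genes that fell included Rgcc, a regulator of the cell cycle (10.3-fold, 5.42 to 19.7), Ubd, a ubiquitin-like modifier (at least 4.61-fold), and Ivns1abp (6.08-fold, 4.01 to 9.21). Also lower were Arhgap30 (5.50-fold, 3.31 to 9.12), Steap2 (5.11-fold, 2.96 to 8.83) and Calca, which encodes calcitonin and the peptide CGRP (4.95-fold, 2.99 to 8.19). Thumpd1, Baiap2l1, Slc4a3, Pnpla3, Aqr, Tomm22, Olig1 and Ubd kept their calls whichever array was left out. Without control iPS replicate 1 the calls of Cd3d (highest adjusted p over such fits 0.191), Cd3g (0.0828), Akr1c18 (0.149), Olfml1 (0.112), Cited4 (0.0901), Arhgap30 (0.103), Steap2 (0.148), Calca (0.149), Rgcc (0.0918) and Ivns1abp (0.0762) ended. So did, of these, Cd3d, Akr1c18, Olfml1 and Calca without control iPS replicate 2, all but Cd3d and Cd3g without ES replicate 2, and all but Cd3g, Rgcc and Ivns1abp without either Oct4-low iPS array. The count itself ran from 14 without control iPS replicate 1 to 244 without ES replicate 1. It was 55 without control iPS replicate 2, 22 without ES replicate 2 and 35 without either Oct4-low iPS array.

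Neural genes were lower in control iPS than in ES cells. Of 8 measured, 3 fell, all of them transcription factors of neural progenitors. They were Olig1 (at least 4.66-fold, adjusted p = 0.00114), Sox11 (5.85-fold, 3.73 to 9.17, adjusted p = 0.0151) and Sox4 (at least 3.27-fold, adjusted p = 0.0181). The list had a median log2 difference of -0.70, also with bounded genes at their bound, and was shifted down by camera (adjusted p = 0.0163, adjusted p = 0.909 with an estimated correlation). Adjusted over the list alone, 3 fell and 1 rose. The genes of ATF4 and amino acid stress were shifted down as a list (median -0.61, -0.57 with bounds, camera adjusted p = 0.000827), with 1 of 18 members above 0 (adjusted p = 0.909 with an estimated correlation). Of those 18, limma called 0 over all genes, 5 had an unadjusted p under 0.05, all lower, and 2 fell adjusted over the list alone. Mthfd2, a mitochondrial folate enzyme, differed by -1.11 (adjusted p = 0.0921). Epithelial and adhesion genes were likewise shifted down (median -0.58, -0.55 with bounds, camera adjusted p = 0.00206, adjusted p = 0.909 with an estimated correlation), with 2 of 16 members above 0. Of these, limma called 0, 5 had an unadjusted p under 0.05, all lower, and 1 fell adjusted over the list alone. The trophectoderm list was not shifted (camera adjusted p = 0.198), yet Gata3, a trophectoderm factor, rose at least 2.21-fold (adjusted p = 0.0405). It was the 1 call among 18 members over all genes, against 5 rises adjusted over the list alone. The other 24 lists were not shifted and had no called member. The lowest adjusted p among them was 0.0847, for two-cell-like genes, of which 9 of 9 were above 0 (median 0.68). That median rested on the ES arrays, at 1.55 without ES replicate 1 (adjusted p = 0.000642) and -0.03 without ES replicate 2 (0.856), and the list passed without either Oct4-low iPS array (0.0180) and with no filter on dim probes (0.00243). Other lists passed without 1 array. These were the cholesterol, general pluripotency and glycolysis lists without control iPS replicate 2 (0.00682, 0.0330 and 0.00910) or ES replicate 1 (0.00433, 0.0162 and 0.0111) and the germline list without ES replicate 2 (0.0142). The mesendoderm list passed without either Oct4-low iPS array (0.0222). The trophectoderm list (median 0.13) passed without control iPS replicate 1 (median 0.44, adjusted p = 0.0180), without the genes of chromosomes 6, 8 and X (median 0.45, adjusted p = 0.0390) and with no filter on dim probes (median 0.24, adjusted p = 0.00484). With no filter the cholesterol (0.0414) and Wnt (0.0367) lists passed too. The call of the ATF4 list ended without control iPS replicate 1 (median -0.17, adjusted p = 0.344), and its median was -1.05 without control iPS replicate 2 and -0.39 without ES replicate 2. That of the epithelial list ended without control iPS replicate 1 or ES replicate 2 (medians -0.29 and -0.22, adjusted p up to 0.148) and with genes detected on all 6 arrays (0.0870). That of the neural list ended without ES replicate 1 (0.0771) and with no filter on dim probes (median -0.07, adjusted p = 0.101), and its median was -0.36 without control iPS replicate 1. Without background correction the neural median was -0.33 and the epithelial median -0.36. Among the genes, Sox11 lost its call without ES replicate 2 (0.0664), Sox4 without that array or either control iPS array (up to 0.103), and Gata3 without any array but control iPS replicate 2 (up to 0.200).

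Oct4-low iPS cells were compared with ES cells to ask how the line with the lowest Pou5f1 signal differs from the reference. With a single line in each group, the Oct4 level cannot be told apart from other traits of the line. Ly6a, the surface antigen Sca-1, rose 41.2-fold, from 5.77 ± 0.50 in ES to 11.13 ± 0.84 in Oct4-low iPS cells (18.8 to 90.2, adjusted p = 0.00295). Its ES signal lay near the lowest detected signal of the ES arrays, 5.43 and 5.45, and no bound was applied. The size of this fold is therefore uncertain. Otx2, a transcription factor of the epiblast as it leaves the naive state, rose 6.58-fold (4.37 to 9.91, adjusted p = 0.00335). The primitive endoderm factor Gata6 rose 4.86-fold (2.80 to 8.43, adjusted p = 0.0155), while it differed by 0.28 between control iPS and ES cells (adjusted p = 0.740). Among the falls, Pou5f1 itself stood beside Sox11 (at least 8.18-fold lower, adjusted p = 0.00179), Fah, the last enzyme of tyrosine breakdown (12.8-fold, 7.72 to 21.2, adjusted p = 0.00265), and Fstl1, a secreted follistatin-like protein (8.83-fold, 5.83 to 13.4, adjusted p = 0.00261). In all, 591 genes changed, 309 up and 282 down, and 176 had a bound. At an unadjusted p under 0.05 there were 2274. The count of calls was 191 with no filter on dim probes, 288 with detection on all 6 arrays and 1015 with the replicate number as a block.

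The remaining large rises in Oct4-low iPS over ES cells were Thumpd1 (at least 8.39-fold), Klra1, a receptor of natural killer cells (at least 8.82-fold), Spic, an Ets-family transcription factor (15.3-fold, 7.15 to 32.7), Fbp2, the muscle fructose bisphosphatase (14.6-fold, 7.95 to 26.9), and Art3 (at least 8.44-fold). With them rose Baiap2l1 (12.7-fold, 8.74 to 18.3), Pdlim4 (11.2-fold, 5.15 to 24.6), Ffar2, a receptor for short-chain fatty acids (at least 6.24-fold), and Nnmt, which methylates nicotinamide (at least 8.42-fold). The remaining large falls were Tomm22 (31.8-fold, 22.7 to 44.6, with 0.49 in the opposite direction by its other probe), Pla2g1b, a secreted phospholipase (11.7-fold, 4.84 to 28.3), and Olig1 (at least 4.88-fold). With them fell Trh, thyrotropin-releasing hormone (8.78-fold, adjusted p = 0.0158), Evc2, a ciliary protein of hedgehog signalling (at least 4.45-fold), and Calca (8.26-fold, adjusted p = 0.00488). Of the 20 largest changes, 15 kept their call whichever array was left out. The other 5 lost it without Oct4-low iPS replicate 2, and some also without other arrays, namely Spic (0.0672), Pla2g1b (0.0704, also without ES replicate 2), Pdlim4 (0.0953) and Trh (0.114), both also without Oct4-low iPS replicate 1 or ES replicate 2, and Nnmt (0.138, also without either ES array). The count ran from 74 without Oct4-low iPS replicate 2 to 622 without ES replicate 1. It was 143 without Oct4-low iPS replicate 1 and 182 without ES replicate 2.

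Extraembryonic lists were higher and the ERK list was lower in Oct4-low iPS than in ES cells. Trophectoderm genes were shifted up (median 0.82, 0.64 with bounds, camera adjusted p = 0.00584, adjusted p = 0.784 with an estimated correlation), and 14 of 18 were above 0. Those that rose were the matricellular protein gene Tinagl1 (7.71-fold, 3.74 to 15.9, adjusted p = 0.0157) and the transcription factor gene Tfap2a (2.63-fold, adjusted p = 0.0143). That makes 2 over all genes, against 8 rises and 1 fall adjusted over the list alone. Primitive endoderm genes were shifted up (median 0.32, camera adjusted p = 0.0175, adjusted p = 0.784 with an estimated correlation). Of 11, 3 rose, namely Gata6, Dab2, an endocytic adaptor (4.53-fold, 2.82 to 7.29, adjusted p = 0.0112), and Sparc, a matrix protein (2.05-fold, adjusted p = 0.0484). Adjusted over the list alone, 4 rose. ERK response genes were shifted down (median -1.04, -0.63 with bounds, camera adjusted p = 0.00584, adjusted p = 0.906 with an estimated correlation), with 0 of 11 above 0. The 1 that fell was Spred1, an inhibitor of Ras and ERK signalling (2.89-fold lower, adjusted p = 0.0171), and 3 fell adjusted over the list alone. Dusp6, the phosphatase of ERK, differed by -1.93 (adjusted p = 0.103). Leaving out 1 array ended the calls of Tinagl1 (without either Oct4-low iPS array or ES replicate 2, up to 0.115), Spred1 (the same arrays, 0.127), Tfap2a (Oct4-low iPS replicate 2, 0.111), Dab2 and Gata6 (Oct4-low iPS replicate 1, 0.0651 and 0.0699) and Sparc (any of the 4 arrays compared, 0.261). The ERK list call ended without ES replicate 2 (median -0.67, adjusted p = 0.116) and the trophectoderm call with genes detected on all 6 arrays (median 0.16, adjusted p = 0.348). The primitive endoderm list kept its call, with a median of 0.64 without Oct4-low iPS replicate 1, 0.55 and 0.58 without ES replicates 1 and 2, and 0.13 with no filter on dim probes. With no filter the trophectoderm median was 0.26 and the ERK median -0.63, and without background correction they were 0.40 and -0.49. Without ES replicate 1 the cholesterol, glycolysis and two-cell-like lists passed (0.00685, 0.00685 and 0.00949), the last of them also without Oct4-low iPS replicate 2 (0.0146). With no filter the cholesterol (0.0389) and neural (0.0492) lists passed.

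Of the 22 general pluripotency genes, 3 fell in Oct4-low iPS compared with ES cells and 4 when adjusted over the list alone. The calls included Phc1, a subunit of Polycomb complex PRC1 (3.20-fold, adjusted p = 0.00848), on chromosome 6, whose genes had a median of -0.35, and Lin28a, an RNA-binding protein that blocks let-7 (2.99-fold, adjusted p = 0.0272). As a list they did not pass camera (median -0.34, adjusted p = 0.0823), but did without Oct4-low iPS replicate 1 (0.00817) or ES replicate 2 (median -0.73, adjusted p = 0.00304). They also passed with no filter on dim probes (0.0335) and with the replicate number as a block. The median was -0.20 without Oct4-low iPS replicate 2, -0.02 without ES replicate 1 and -0.10 without the genes of chromosomes 6, 8 and X (adjusted p = 0.384). Of 15 Oct4-Sox2 target genes, 1 fell over all genes, while 1 rose and 3 fell adjusted over the list alone. Of 8 primed epiblast genes, Otx2 rose and Pou3f1, the POU factor Oct6, fell at least 1.51-fold (adjusted p = 0.0476), with 1 rise and 2 falls adjusted over the list alone. Of 8 neural genes, Sox21 rose (2.44-fold, adjusted p = 0.0316) while Olig1, Sox11 and Sox4 (3.77-fold, adjusted p = 0.0143) fell, with the same counts adjusted over the list alone. Of 4 mesendoderm genes, Gsc, the organizer homeobox gene, rose 7.05-fold (3.57 to 13.9, adjusted p = 0.0155), and 2 rose adjusted over the list alone. Among 34 cell cycle genes Mki67 fell 1.92-fold (adjusted p = 0.0458; 0 adjusted over the list alone, and 7 at an unadjusted p under 0.05). Among 20 glycolysis genes Pdk1 fell 2.39-fold (adjusted p = 0.0127; 1 adjusted over the list alone). Among 16 epithelial and adhesion genes the splicing regulator Esrp1 fell 2.88-fold (adjusted p = 0.0263; 1 adjusted over the list alone). These calls each ended without Oct4-low iPS replicate 2, save those of Otx2, Olig1 and Sox11, which were kept whichever array was left out. The highest adjusted p on leaving out any 1 array was 0.0676 for Phc1, 0.148 for Lin28a, 0.276 for Pou3f1, 0.205 for Sox21, 0.0827 for Sox4, 0.112 for Gsc, 0.220 for Mki67, 0.111 for Pdk1 and 0.145 for Esrp1. Other arrays also ended them, with Oct4-low iPS replicate 1 doing so for all but Phc1 and Lin28a and ES replicate 1 for Lin28a and Mki67. The same held of ES replicate 2 for Lin28a, Pou3f1, Sox21, Pdk1, Esrp1 and Mki67, and either control iPS array for Pou3f1 and Mki67.

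The iPS lines were compared with each other to ask how the clone marked low differs from the control line that carries the same kind of transgene. Rgcc was 23.0-fold higher in Oct4-low than in control iPS cells (12.0 to 43.8, adjusted p = 0.00463) and Fstl1 was 22.4-fold lower (14.8 to 33.9, adjusted p = 0.00245). Actn2, the alpha-actinin of muscle sarcomeres, rose 9.16-fold (6.22 to 13.5, adjusted p = 0.00415), and Otx2 rose 5.85-fold (3.88 to 8.81, adjusted p = 0.00795). Phc1 fell 2.88-fold (2.05 to 4.05, adjusted p = 0.0176). In all, 311 genes changed, 154 up and 157 down, and 118 had a bound. At an unadjusted p under 0.05 there were 1859. The count of calls was 58 with no filter on dim probes, 126 with detection on all 6 arrays and 769 with the replicate number as a block. Without the genes of chromosomes 6, 8 and X, a setting added after the values were seen, 205 changed.

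Further rises in Oct4-low over control iPS cells were Klra1 (at least 8.19-fold), Art3 (at least 7.83-fold), Ly6a (12.0-fold, 5.47 to 26.3), and Ffar2 (at least 5.79-fold). So were Slc1a1, a glutamate transporter (at least 4.46-fold), Gpat3, an enzyme of triglyceride synthesis (8.06-fold, 4.98 to 13.0), Adh1, an alcohol dehydrogenase (at least 4.44-fold), and Pdlim4 (6.46-fold, 2.96 to 14.1). Further falls were Akr1c18 (9.07-fold, 4.44 to 18.5), Rerg, a Ras-like GTPase (at least 5.33-fold), and Sall3 (7.61-fold, 4.28 to 13.5). Pcyt1b, an X-linked enzyme of phosphatidylcholine synthesis, fell 7.15-fold (4.76 to 10.7). Nt5e, the ecto-nucleotidase CD73 (at least 4.60-fold), Adcy2, an adenylyl cyclase (at least 4.48-fold), Ank, which exports pyrophosphate (at least 4.72-fold), and Hopx, a homeodomain protein that does not bind DNA (at least 3.75-fold), fell as well. Rgcc, Klra1, Art3, Ffar2, Actn2, Slc1a1, Fstl1, Rerg, Pcyt1b and Ank kept their calls whichever array was left out. The calls of Ly6a (0.0944) and Adh1 (0.0844) ended without control iPS replicate 1 or Oct4-low iPS replicate 2, and that of Sall3 (0.0826) without replicate 1 of either line. Those of Gpat3 (0.0703) and Hopx (0.0864) ended without Oct4-low iPS replicate 2, and those of Pdlim4 (0.240), Akr1c18 (0.139), Nt5e (0.163) and Adcy2 (0.197) without control iPS replicate 1 or either Oct4-low iPS array. The count fell to 35 without control iPS replicate 1, 62 without Oct4-low iPS replicate 1 and 37 without Oct4-low iPS replicate 2, and was 287 without control iPS replicate 2 and 413 without either ES array.

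General pluripotency genes were lower in Oct4-low than in control iPS cells. Of 22, 3 were above 0, the median was -0.58, and camera gave an adjusted p of 0.000329 (adjusted p = 0.549 with an estimated correlation). Of these, 2 fell, Phc1 among them, and 4 fell adjusted over the list alone. Primitive endoderm genes were higher (median 0.90, camera adjusted p = 0.00184, adjusted p = 0.549 with an estimated correlation). Gata6 (3.99-fold, 2.30 to 6.92, adjusted p = 0.0334) and Dab2 (at least 3.78-fold, adjusted p = 0.0130) rose among 11. In all 7 rose and 1 fell adjusted over the list alone. Epithelial and adhesion genes were higher (median 0.51, 0.37 with bounds, camera adjusted p = 0.00184, adjusted p = 0.549 with an estimated correlation), with 15 of 16 above 0. The 1 that rose, also adjusted over the list alone, was Cdh3 on chromosome 8, whose genes had a median of 0.17; it encodes P-cadherin (at least 2.93-fold, adjusted p = 0.0154). ERK response genes were lower (median -0.86, -0.73 with bounds, camera adjusted p = 0.00604, adjusted p = 0.549 with an estimated correlation). Spred1 fell 2.64-fold (adjusted p = 0.0334), 1 of 11 members was above 0, and 3 fell adjusted over the list alone. Leaving out control iPS replicate 1 ended the epithelial (median 0.32, adjusted p = 0.0572) and ERK (median -0.51, adjusted p = 0.142) list calls, and the former ended also with genes detected on all 6 arrays (median 0.33, adjusted p = 0.321) and had a median of 0.89 without control iPS replicate 2. The general pluripotency median was -0.37 without control iPS replicate 1 and -0.36 without Oct4-low iPS replicate 2. The primitive endoderm median was 0.59 without control iPS replicate 1, 0.57 without background correction and 0.11 with no filter on dim probes, where the ERK median was -0.57. Leaving out control iPS replicate 1 ended the gene calls of Phc1 (highest adjusted p over such fits 0.131), Otx2 (0.0703), Gata6 (0.164), Spred1 (0.222) and Cdh3 (0.0955). Leaving out Oct4-low iPS replicate 2 also ended these gene calls, and leaving out its replicate 1 those of Phc1, Otx2, Gata6 and Spred1. Dab2 lost its call only without Oct4-low iPS replicate 1 (0.0684), and Gata6 and Spred1 lost theirs also without control iPS replicate 2.

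Among 18 trophectoderm genes, which were not shifted as a list between the iPS lines (camera adjusted p = 0.191), the homeobox gene Rhox9, which is X-linked, rose 5.42-fold (2.85 to 10.3, adjusted p = 0.0283). The galectin gene Lgals3 fell 4.47-fold (2.42 to 8.26, adjusted p = 0.0360). Adjusted over the list alone, 5 rose and 3 fell. Of 15 Oct4-Sox2 target genes, 2 fell, Hopx among them, with 1 rise and 3 falls adjusted over the list alone (camera adjusted p = 0.226). Otx2 was the 1 primed epiblast gene of 8 to change, and Sox11 (at least 1.40-fold lower, adjusted p = 0.0470) the 1 neural gene of 8. Adjusted over the list alone, 1 primed gene rose, and 1 neural gene rose and 1 fell. Lefty1, a Nodal antagonist, differed by -3.35 (adjusted p = 0.0605) and Gbx2, a LIF-responsive homeobox gene, by -2.26 (adjusted p = 0.0560), both short of the threshold. The calls of Rhox9 (up to 0.148), Lgals3 (0.220) and Sox11 (0.254) ended without control iPS replicate 1 or Oct4-low iPS replicate 2, those of the latter pair also without Oct4-low iPS replicate 1. The 18 lists that were neither shifted nor held a called member included the ATF4 list (camera adjusted p = 0.0772; median 0.37), which passed without control iPS replicate 2 (3.29e-05) or Oct4-low iPS replicate 1 (0.00845). The glycolysis list passed without control iPS replicate 1 (0.00950), the two-cell-like list without Oct4-low iPS replicate 1 (0.0218) and the Wnt list without Oct4-low iPS replicate 2 (0.0310) or with no filter on dim probes (0.0151). With an estimated correlation, camera called 0 of 28 lists in each of the 3 comparisons, and 1 list in each had an unadjusted p under 0.05. This does not show that correlation removes the shifts, since that setting also rests on 3 residual degrees of freedom. The trophectoderm list in Oct4-low iPS over ES cells had an estimated correlation of -0.00716, below the preset one. Its unadjusted camera p still went from 0.000247 to 0.0287. With the preset correlation 7, 6 and 7 lists had an unadjusted p under 0.05.

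**Figure D2:**
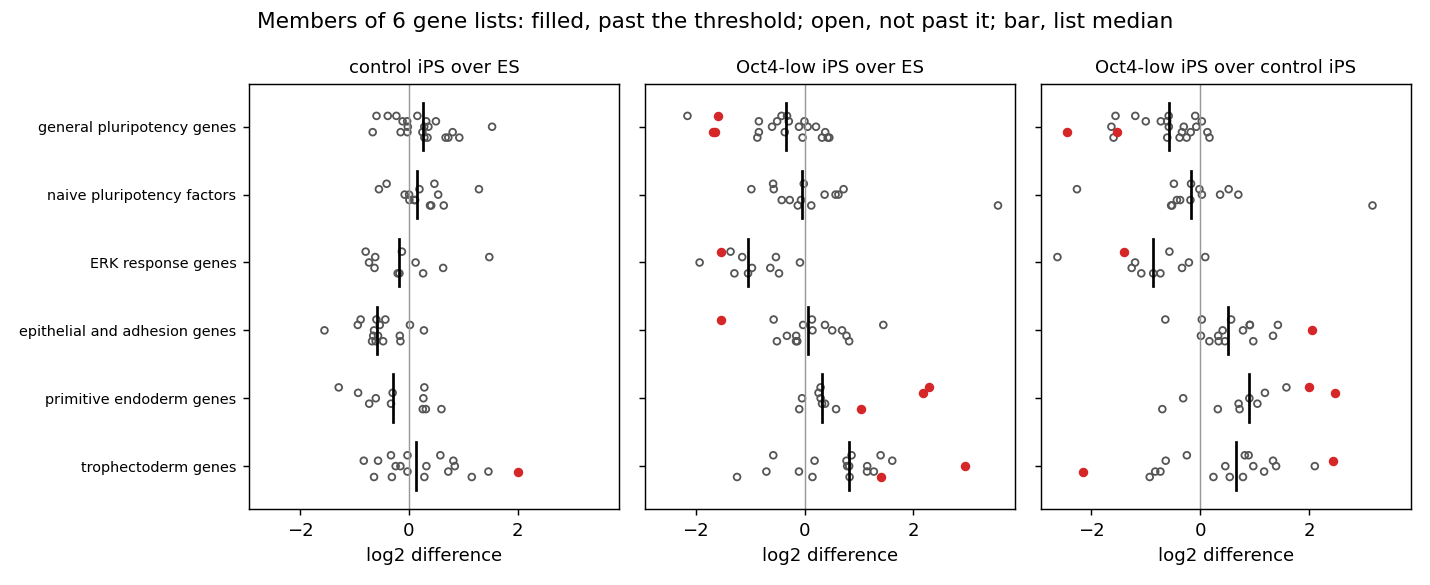
Log2 difference (horizontal axis) of every measured member of 6 gene lists (vertical axis) in the 3 comparisons; filled red points passed an adjusted p of 0.05 over all genes, open points did not, and each bar is the list's median. Between the iPS lines the median is -0.58 for general pluripotency genes and 0.90 for primitive endoderm genes.

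In both iPS lines 3 genes changed against ES cells in opposite directions, where unrelated lists of these sizes would share 3.22. In the same direction 66 genes changed, 30 up and 36 down, where unrelated lists would share 3.23. Because both comparisons use the same 2 ES arrays, part of this excess may arise from the shared reference. In 100 simulations of groups without any change, which leave out each line's own changes, the mean was 0.01 shared genes and the most was 1. Neither number is what the shared arrays and real changes give together, so the excess over them is not a count of shared effects. Across genes, which are not independent replicates, the log2 differences correlated with r = 0.54 against 0.50 simulated, with a covariance of 0.154 against 0.0308. The simulation gave all arrays the same spread for a gene. The real replicate differences had an SD of 0.461 in ES, 0.425 in control iPS and 0.343 in Oct4-low iPS cells. A wider spread of the shared ES arrays raises both simulated values, so the gap in r is no evidence of shared effects. Tomm22, Thumpd1, Baiap2l1, Olig1, Ubd, Slc4a3, Sox11, Ly6e, Aqr and Pnpla3 had the largest shared changes. Ly6e, a relative of Ly6a, rose 5.29-fold in control iPS (3.68 to 7.59) and 7.17-fold in Oct4-low iPS cells (4.99 to 10.3), and its other probe differed by 2.61 on average over both. Of the 66, 61 were not called between the iPS lines and 5 were, among them Sox11. The shared genes numbered 19 with no filter on dim probes, 17 with detection on all 6 arrays and 181 with the replicate number as a block. By their other detected probes, Slc4a3 moved in the same direction and Tomm22 and Aqr did not. Ly6e lost its call in control iPS cells without control iPS replicate 1 (0.0762), and Sox11 without ES replicate 2 (0.0664). The shared count was 14 without control iPS replicate 1, 36 without control iPS replicate 2, 21 and 19 without Oct4-low iPS replicates 1 and 2, 157 without ES replicate 1 and 20 without ES replicate 2.

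Genes of chromosomes 6, 8 and X differed as blocks in some comparisons. In control iPS over ES cells the median log2 difference was -0.32 over 442 genes of chromosome 6 (-0.36 to -0.29), -0.33 over 531 genes of chromosome 8 (-0.36 to -0.31) and 0.34 over 327 genes of the X chromosome (0.29 to 0.38). The medians of the other 17 autosomes lay between -0.03 and 0.05 there, between -0.09 and 0.02 in Oct4-low iPS over ES cells and between -0.07 and 0.03 between the iPS lines. In Oct4-low iPS over ES cells the medians were -0.35 for chromosome 6 (-0.38 to -0.31), -0.15 for chromosome 8 (-0.19 to -0.10) and -0.14 for the X chromosome (-0.20 to -0.09). Between the iPS lines X-linked genes were lower in Oct4-low cells (median -0.52, -0.57 to -0.45; 3 rose and 33 fell). Chromosome 8 genes were higher (median 0.17, 0.13 to 0.21; 20 rose and 3 fell) and chromosome 6 genes had a median of -0.01 (-0.05 to 0.03). With the preset correlation camera gave adjusted p of 1.11e-11, 8.93e-15 and 3.72e-12 for chromosomes 6, 8 and X in control iPS over ES cells. In Oct4-low iPS over ES cells chromosome 6 (3.36e-07) and X (0.0202) passed and chromosome 8 did not (0.0722). Between the iPS lines X (7.37e-21) and chromosome 8 (1.33e-05) passed and chromosome 6 did not (0.973). With an estimated correlation none passed, with adjusted p of 0.302, 0.769 and at least 0.632 in the 3 comparisons. That setting rests on 3 residual degrees of freedom, so little can pass it. The 2 ES arrays themselves differed by a median of 0.17 on chromosome 6, 0.11 on chromosome 8 and -0.16 on X, and the 2 control iPS arrays by -0.19 on X. The intervals of the medians take genes as independent and leave out this spread between arrays.

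**Figure D3:**
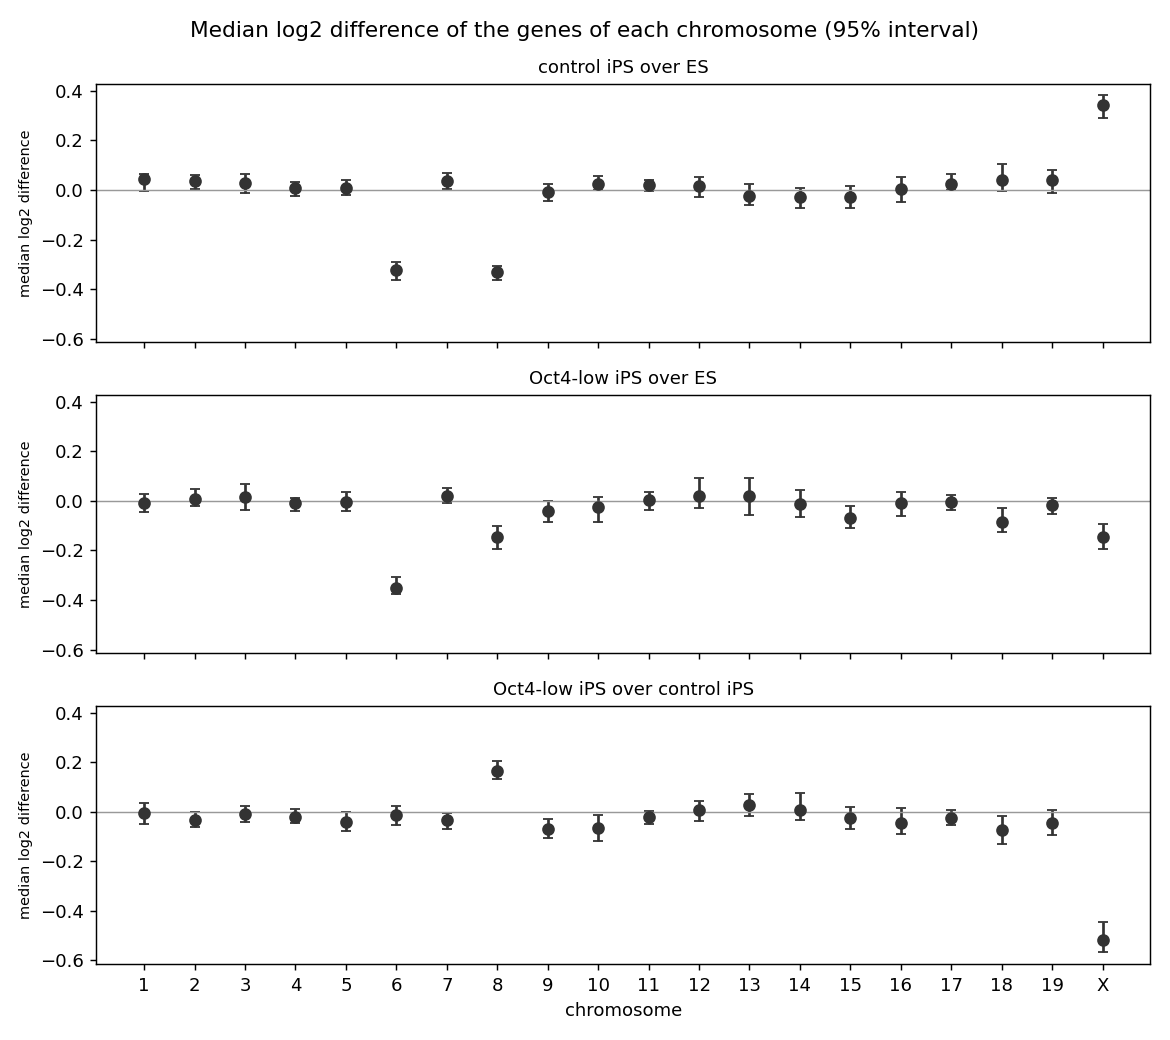
Median log2 difference (vertical axis) of the measured genes of each of 20 chromosomes (horizontal axis) in the 3 comparisons. Points are medians and bars their 95% interval over genes, without the spread between arrays. Chromosomes 6 and 8 stand at -0.32 and -0.33 in control iPS over ES cells, and X stands at -0.52 in Oct4-low over control iPS cells.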

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

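None of the tests of the following genes was chosen after the result had been seen.

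A trio of genes stood out because the iPS lines moved them in opposite directions against ES cells. Unrelated lists as long as those of the genes changed against ES cells would share 3.22 such genes. In the one model used, the difference between the lines adds up the sizes of both differences against ES cells. That it passed its test thus follows from how the genes were picked and is no added support. Rerg, a Ras-like GTPase gene on chromosome 6, was 3.27-fold higher in control iPS (2.36 to 4.53) and at least 1.63-fold lower in Oct4-low iPS than in ES cells, and at least 5.33-fold lower in Oct4-low than in control iPS cells (adjusted p = 0.00245), where the fitted log2 difference of -3.03 rests on signals at background and is no measured size. Ank, the pyrophosphate transporter gene, was 2.74-fold higher in control iPS (1.87 to 4.01) and at least 1.72-fold lower in Oct4-low iPS than in ES cells, and at least 4.72-fold lower in Oct4-low than in control iPS cells (adjusted p = 0.00463), with a fitted -2.66 of the same kind. Gca, which encodes the calcium-binding protein grancalcin, was 2.30-fold lower in control iPS (1.71 to 3.10) and 2.11-fold higher in Oct4-low iPS than in ES cells (1.56 to 2.84), with a log2 difference of 2.28 between the lines (adjusted p = 0.00450). The calls between the lines held for all 3 genes whichever array was left out. The calls of control iPS against ES cells did not: Rerg lost its own without control iPS replicate 1, ES replicate 2 or either Oct4-low iPS array (adjusted p up to 0.102), Ank without any array but ES replicate 1 (up to 0.214) and Gca without any 1 array (up to 0.205). Against ES cells in Oct4-low iPS, Rerg lost its call without either Oct4-low iPS array (up to 0.102), Ank also without either ES array (up to 0.216), and Gca without either Oct4-low iPS array or ES replicate 2 (up to 0.140).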

How the results depend on the processing

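The setting without the genes of chromosomes 6, 8 and X was chosen after the data were seen. Over the settings that kept each count within 1.5 times, the genes changed, or probes with the authors' values or every probe as a feature, numbered 86 to 159 in control iPS over ES, 468 to 823 in Oct4-low iPS over ES and 290 to 413 in Oct4-low over control iPS, and 60 to 95 were shared. With no filter on dim probes, which adds genes never above background, the counts were 24, 191 and 58, with 19 shared, and 6 and 7 lists were shifted in the comparisons against ES. With genes detected on all 6 arrays they were 22, 288 and 126, with 17 shared and 1 list shifted in control iPS over ES; this removes genes that were off in a group. With only the 4 arrays compared, 35 genes changed in control iPS over ES, and Pou5f1 (-1.20) was no longer past the threshold (adjusted p = 0.0868); 1 group fewer gives the spread. With the replicate number as a block the counts were 331, 1015 and 769, with 181 shared and 5 lists shifted in Oct4-low iPS over ES. Among named genes the block kept all 110 calls and gained 57. That block also called the two-cell-like list in control iPS over ES, general pluripotency and Nodal in Oct4-low iPS over ES, and Nodal and ATF4 between the lines. The labels say only that replicates share a number; with 2 pairs per comparison, the differences between a group's replicates correlated across genes by 0.34 between the iPS lines, 0.35 between control iPS and ES and 0.20 between Oct4-low iPS and ES, a hint of a shared replicate effect. The authors' values gave 198 probes in Oct4-low over control iPS, and without chromosomes 6, 8 and X 205 genes changed there; the cause of the former was not tested. An estimated correlation left 0, 0 and 0 lists. With its 3 residual degrees of freedom, that setting cannot show that correlation is the reason. Leaving out 1 array at a time, with a lone sample assumed to vary like the other groups, gave 14 to 244, 74 to 622 and 35 to 413 genes, 14 to 157 shared, and 2 to 7, 3 to 7 and 4 to 6 lists, while Pou5f1 ranged from -1.24 to -1.16, -3.32 to -3.23 and -2.12 to -2.03. Another probe reversed Aqr (-0.29 in control iPS and -0.71 in Oct4-low iPS over ES), Tomm22 (0.34 and 0.49) and Actb (0.94 in Oct4-low iPS over ES, against -0.51 by the probe used, which was not called); the cause was not tested. Of 206 values by other probes, 53 belonged to calls, of which 35 still passed, 14 did not and the rest reversed; no other setting reversed a named gene. With no filter, 60 of 110 calls of named genes were lost; dim signal, the larger number of tests and the changed prior were not separated. Not run were the chip as a block, since no chip is named, and, with the authors' values, the lists, the named genes and Pou5f1, since identifiers there were not paired with genes. Lists were also not run on only 4 arrays, on single probes or with the log2 minimum, and the overlap not on only 4 arrays.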

Other observations

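The chromosome medians were examined, and the tests of a missing Y chromosome and of chromosome 8 in Oct4-low iPS cells were chosen, after the results had been seen.

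A few imprinted genes changed in Oct4-low iPS cells, in both directions. Usp29 and Peg3, which share an imprinted region of chromosome 7, moved apart. Usp29 rose at least 2.10-fold in Oct4-low iPS over ES cells (adjusted p = 0.00673) and at least 1.94-fold over control iPS cells (adjusted p = 0.0122). Peg3, a zinc-finger gene, fell 1.92-fold (adjusted p = 0.0485) and 2.93-fold (2.09 to 4.11, adjusted p = 0.0171) in the same comparisons. Phlda2, a gene that limits placental growth, fell 4.11-fold against ES cells (2.34 to 7.21, adjusted p = 0.0222). Slc38a4, an amino acid transporter gene, rose at least 1.95-fold against control iPS cells (adjusted p = 0.0110). Of 22 imprinted genes, 1 rose and 2 fell in Oct4-low iPS over ES cells, against 3 and 4 adjusted over the list alone. Between the iPS lines 2 rose and 1 fell, against 2 and 2. In control iPS over ES cells limma called 0, with 5 at an unadjusted p under 0.05 and 1 that fell adjusted over the list alone. The list was not shifted (camera adjusted p = 0.779, 0.759 and 0.456 in control iPS over ES, Oct4-low iPS over ES and between the lines). Against ES cells, Usp29 lost its call without Oct4-low iPS replicate 2 (0.0540), Phlda2 without that array or ES replicate 2 (up to 0.0959) and Peg3 without any 1 array (up to 0.226). Between the lines all 3 calls ended without control iPS replicate 1 or Oct4-low iPS replicate 2, and those of Peg3 and Slc38a4 also without Oct4-low iPS replicate 1 (up to 0.0864 for Usp29, 0.117 for Peg3 and 0.0879 for Slc38a4).

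Polycomb subunits moved apart as well. In Oct4-low iPS over ES cells Phc1 fell 3.20-fold and Phf19, a chromatin reader of PRC2, at least 1.54-fold (adjusted p = 0.0339), while Phc2, a relative of Phc1, rose 1.93-fold (1.48 to 2.52, adjusted p = 0.0239). That is 1 rise and 2 falls among 16, also adjusted over the list alone (camera adjusted p = 0.863). Between the iPS lines Phc1 fell and was the 1 call by either adjustment. Among 9 Wnt target genes the 1 call against ES cells was Notum, a feedback inhibitor of Wnt, which rose 3.02-fold (1.73 to 5.28, adjusted p = 0.0454), and 2 rose and 1 fell adjusted over the list alone. Among 13 germline genes the 1 call was X-linked Tex11, at least 1.46-fold lower (adjusted p = 0.0484), with 1 rise and 2 falls adjusted over the list alone. Dppa3, also a germline and naive gene, measured 9.79 ± 0.93 in Oct4-low iPS and 6.24 ± 1.65 in ES cells (adjusted p = 0.0533). The calls of Notum (up to 0.260), Phc2 (0.171) and Phf19 (0.176) ended without either Oct4-low iPS array or ES replicate 2. That of Tex11 ended without any of the 4 arrays compared (0.260) and that of Phc1 without Oct4-low iPS replicate 2 (0.0676 against ES, and up to 0.131 between the lines, where control iPS replicate 1 and Oct4-low iPS replicate 1 ended it too).

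Several lists had 0 genes called by limma in each comparison. Counts at an unadjusted p under 0.05 are given for control iPS over ES, Oct4-low iPS over ES and Oct4-low over control iPS, in that order. Fibroblast and feeder cell genes had 3, 5 and 5 of 10 (camera adjusted p = 0.766, 0.812 and 0.937), and 1 fell in each comparison of Oct4-low iPS cells adjusted over the list alone. Interferon response genes had 1, 0 and 2 of 11 (camera adjusted p = 0.463, 0.679 and 0.221), with 1 fall between the lines over the list alone. LIF-STAT3 response genes had 2, 4 and 5 of 13 (camera adjusted p = 0.974, 0.882 and 0.937), with 2 rises and 2 falls against ES in Oct4-low iPS, and 2 rises and 1 fall between the lines, over the list alone. Nodal target genes had 1, 3 and 2 of 6 (camera adjusted p = 0.778, 0.0792 and 0.137), with 1 fall over the list alone in each comparison of Oct4-low iPS cells. The Nodal list passed against ES cells without Oct4-low iPS replicate 2 (0.00387), ES replicate 1 (0.0462) or the genes of chromosomes 6, 8 and X (0.0462) and without background correction (0.0484), and between the lines without Oct4-low iPS replicate 2 (0.00655) or control iPS replicate 1 (0.0427). BMP target genes had 0, 1 and 0 of 3. DNA methylation machinery had 2, 4 and 2 of 12 (camera adjusted p = 0.766, 0.129 and 0.429), with 2 falls over the list alone in control iPS over ES cells and 2 between the lines, and passed in Oct4-low iPS over ES cells without ES replicate 2 (0.0471) or with no filter on dim probes (0.0155). The p53 target genes had 2, 4 and 2 of 16, oxidative phosphorylation genes 3, 1 and 1 of 34, and cholesterol biosynthesis genes 2, 1 and 2 of 21. Reference genes had 1, 0 and 3 of 13 (camera adjusted p = 0.766, 0.679 and 0.368), with 1 rise and 2 falls between the lines over the list alone. Of the sex-chromosome genes 1 was measured, Ddx3y, and the list was not tested. The median, mean and test of a list differed in sign for the LIF-STAT3 and Wnt lists in control iPS over ES cells, for the naive, germline, Wnt, Polycomb and fibroblast lists in Oct4-low iPS over ES cells, and for the BMP and fibroblast lists between the lines.

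Genes of chromosome 6 in both iPS lines and of chromosome 8 in control iPS cells were lower than in ES cells, and the chromosome 8 median of Oct4-low iPS cells was also below 0, though it did not pass camera (adjusted p = 0.0722). Dim signals do not account for it, since the brightest of 3 bins still had medians of -0.173 (-0.220 to -0.106) or lower. Nor does normalization for chromosome 6 in both lines and chromosome 8 in control iPS cells, where the median nearest to 0 was -0.252 without background correction or with median scaling, but for chromosome 8 in Oct4-low iPS cells the interval around -0.108 (-0.144 to -0.0542) leaves it open. A candidate explanation is a difference in the copy number of whole chromosomes in part or all of the cells. It predicts a fall in each of 4 successive blocks of genes, and the highest block median was -0.134 (-0.212 to -0.0627). The chromosomes were picked by their low medians, and any cause along a whole chromosome predicts the same. The blocks thus show only that the difference was not confined to part of a chromosome. That test used block medians alone, while the one of normalization used the interval too. With an estimated correlation neither chromosome passed camera against ES cells (adjusted p = 0.302 in control iPS and 0.769 in Oct4-low iPS). That setting rests on 3 residual degrees of freedom and settles little. The intervals of the medians are over genes and leave out the spread between arrays. For chromosome 6 the values argue against a graded effect of the Oct4 level. The iPS lines differed there by a median of -0.01 (-0.05 to 0.03 over genes), Oct4-low over control, while their Pou5f1 log2 difference was -2.07. No DNA was measured, the ES arrays themselves differed on both chromosomes, and an effect of the line or any other effect of its Oct4 level was not tested. A difference in copy number therefore stays a hypothesis.

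X-linked genes were higher in control iPS than in Oct4-low iPS cells by a median that normalization does not account for, since it stayed at -0.367 (-0.421 to -0.303) or lower, Oct4-low over control, under both other settings. A difference in X copy number may underlie it, as a hypothesis. All of 4 successive blocks of genes were lower, the highest at -0.413 (-0.538 to -0.345), but any cause along the whole X chromosome predicts this. With an estimated correlation X did not pass camera (adjusted p = 0.632), a setting that rests on 3 residual degrees of freedom. The 2 control iPS arrays themselves differed on X by a median of -0.187 (-0.223 to -0.131), replicate 2 over replicate 1. Each interval here is over genes and leaves out such differences between arrays. Loss of the Y chromosome beside a change of X was tested with Y-linked probes, but 1 of 15, for Ddx3y, was detected on both Oct4-low iPS arrays. That probe was detected on both control iPS arrays too and differed by 0.230, and a single probe leaves the question open. None of the 4 probes of Xist, the RNA that starts X inactivation, was detected on any of the 6 arrays, but no sample known to express Xist was measured, so a change in X inactivation stays open, as do the sex of the lines and an effect of the Oct4 level.

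Genes that changed against ES cells in both iPS lines and not between them could reflect a sequence difference under single probes, for example if the ES cells came from another strain, although all cells were labelled B6. Of 10 other detected probes of 8 such genes, 40% (12.2% to 73.8%, exact binomial) moved by under 0.25 of the used probe's difference or in the other direction. Among genes changed between the iPS lines this was 5.21% of 96 probes (1.71% to 11.7%). Both intervals take probes as independent, although the 10 came from 8 genes and the 96 from 81, so they are too narrow if probes of a gene move together. The other probes of Tomm22 (0.41 against -5.03), Aqr (-0.50 against 2.62), Tubgcp4 (-0.25 against 1.54) and Tmem87a (-0.99 against 1.20) moved apart, while those of Ly6e, Slc4a3, Calca and Clgn moved with them. The interval spans both outcomes set beforehand, so for these genes a probe effect and a difference between the lines and ES cells cannot be told apart, and most of the 61 genes have no other detected probe.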
